A study of Mus musculus with 12 samples.

How the data were processed

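RNA-seq of mouse kidney was analysed in 12 libraries, 3 in each of 4 groups. The groups cross genotype (WT, mice with floxed Wwp2 alleles, against PTCKO, mice with Wwp2 knocked out conditionally in the proximal tubule) with surgery (sham against UIR). Per the labels, the mice were males 8 weeks old. The abbreviation UIR is used as the labels give it, and the time between UIR and tissue collection is not given in the sources used here. Each library was placed in its group by its title. The titles number the libraries within a group, and nothing ties a library to a particular mouse, so p-values measure the spread between these libraries.

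The submitters' processing notes name Bowtie2, RSEM, DESeq2 and the GRCm38.p6 mouse build, without tool versions. The authors deposited 1 table for the series, with an expected count, an FPKM and a TPM value per gene and library and their own group averages, which were not used. The file headers call the count columns read counts, and the processing notes name RSEM. Between 30.8% and 35.4% of a library's values differed from a whole number by more than 1e-06. These columns were therefore taken as RSEM expected counts. The deposited FPKM and TPM values were normalised by the authors for transcript length and library total, per the file headers, which name these units. RSEM shares reads between similar transcripts by estimate, so values of genes with near-identical copies (the beta-globin, histone and Rps27 genes, and members of the Cyp2a, Cyp4a, Mettl7a, Ugt1a and Slc22a families) are uncertain. Whether counting used strand is not given in the sources used here.

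The table held 18803 genes with Entrez identifiers, of which 18747 (99.7%) matched the GRCm38.p6 annotation that supplied coordinates. Transcript lengths were effective lengths computed from the deposited expected counts and FPKM, as the median over libraries. GC content came from a separate set of GENCODE mouse transcript sequences. No gene in the deposited table had the symbol of a mitochondrially encoded gene (0). The list of 13 mitochondrially encoded OXPHOS genes was therefore not analysed here. Lists for perirenal fat and the adrenal gland, tissues that can adhere to a kidney, had 1 of 9 and 1 of 10 members expressed enough to test and were not tested as lists. All count columns were mapped to a library, and 0 columns were left without one.

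Expected counts were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with filterByExpr (15322 genes tested), TMM scaling and 1 coefficient per group fitted to all 12 libraries (8 residual degrees of freedom). Tests were two-sided with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. The 5 comparisons were UIR against sham within each genotype, PTCKO against WT within each surgery, and the interaction, which tests whether the UIR effect differed between genotypes. The design written before the data were examined gave limma on log2(FPKM + 1) as the main test for a table of FPKM alone and edgeR where expected counts were also present. The second case applied, so limma 3.58.1 on genes with FPKM of at least 1 in 3 libraries was run as an alternative.

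The gene lists, the tests, the alternatives and the rule for named genes were also fixed before the data were examined. For each comparison the rule named the 8 largest rises and the 8 largest falls among called genes with a mean FPKM of at least 5 in the higher group. It required no overlap in TMM-scaled CPM between the libraries of the groups compared (a separation that chance gives 10% of the time for 3 against 3), except for the interaction, and left out predicted genes and pseudogenes. The rule also named up to 4 members with the smallest p in each list, and every NEDD4-family ligase. Some genes that the rule named are not reported here. Of the 41 gene lists, 38 had at least 3 tested members. Lists were tested with camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated per list, and with fry, with adjustment over the lists of a comparison. Counts of called members are given over all genes tested and adjusted over the list alone. Levels are FPKM as mean ± SD over 3 libraries. Because FPKM carries no TMM scaling, its ratio between sham and UIR groups differs from the log2 fold changes, which come from edgeR. Fitted fold changes of genes with 0 counts in a group depend on the prior count and set no bound, and levels are given for such genes.

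Totals per library are given with the results. On simulated counts for PTCKO against WT after UIR (about 14960 genes), 50.5% of genes changed 1.5-fold, 78.4% of those changed 2-fold and 99.0% of those changed 4-fold were recovered, with 7.48%, 5.59% and 5.26% of calls false. For the interaction the shares recovered were 4.08%, 62.4% and 89.5%. Each simulation changed 194 to 200 of the genes tested, fewer than were called in the data. Adjusted p depends on that number, so recovery in the data may differ. The smallest difference between replicates, 6.56 chi-square per degree of freedom (WT sham), was above sampling noise, so no library was counted as a copy of another.

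Alternatives were DESeq2 1.42.0, its size factors in edgeR, no count filter, a mean FPKM of at least 5, limma with pseudocounts of 1, 0.1 and 0.01, TPM, quantile normalisation, no trend, array weights, only the groups compared, a replicate block, a 2-fold minimum and leaving out each library in turn. Titles share replicate numbers across groups, so the block on these numbers was planned beforehand. An edgeR fit without scaling factors and the removal of a trend on transcript length and GC content were added after seeing the data.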

Results

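Kidney transcriptomes were measured in 12 libraries from male mice: WT sham, WT UIR, PTCKO sham and PTCKO UIR, with 3 libraries each. The series addresses what Wwp2, a HECT-type ubiquitin ligase of the NEDD4 family, does in the proximal tubule during the passage from acute to chronic kidney disease after UIR. Total expected counts per library were 16411402 to 16953930 in WT sham, 16779444 to 19645743 in WT UIR, 15855889 to 16013920 in PTCKO sham and 15495163 to 19610217 in PTCKO UIR. Replicates correlated at 0.980 to 0.986, and the biological coefficient of variation was 0.121. The first principal component held 85.9% of the variance and parted sham from UIR, and the second held 3.27%. Gpx3 and Kap, 2 abundant proximal tubule transcripts, took 9.25% ± 0.287 of counts in WT sham, 7.82% ± 0.220 in PTCKO sham, 0.757% ± 0.269 in WT UIR and 1.68% ± 0.462 in PTCKO UIR (SD, n = 3). Mean TMM factors, in the same order, were 0.773, 0.846, 1.27 and 1.21. FPKM carries no such factor, so FPKM ratios between sham and UIR differ from the log2 fold changes.

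**Figure D1:**
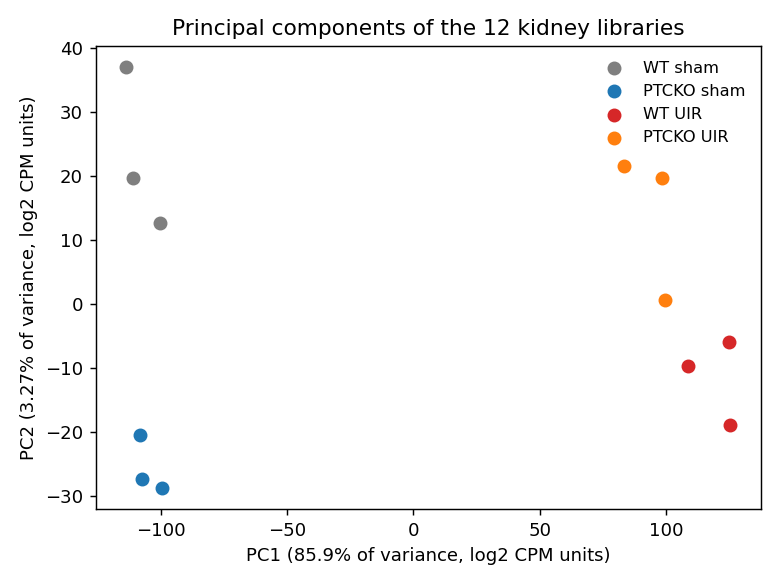
Principal components of the 12 libraries, each point a library, coloured by group, with the percent of variance on each axis. Component 1 (85.9%) separates sham from UIR libraries.

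Wwp2 (Entrez 66894, chromosome 8, 107436334 to 107559290, GRCm38.p6) was not lower in the libraries labelled PTCKO. Its FPKM was 15.18, 15.69 and 17.11 in WT sham, 15.62, 16.09 and 17.61 in PTCKO sham, 17.64, 19.15 and 17.91 in WT UIR, and 22.28, 19.27 and 20.53 in PTCKO UIR. PTCKO differed from WT by a log2 fold change of -0.03 after sham (SE 0.0733, edgeR adjusted p = 0.823) and 0.25 after UIR (SE 0.0728, adjusted p = 0.037). The call after UIR was lost without scaling (0.18, adjusted p = 0.111) and with limma on FPKM (0.17, adjusted p = 0.141). It was also lost without WT sham 1 (0.25), WT UIR 1 (0.23), WT UIR 3 (0.26), PTCKO sham 1 (0.25), PTCKO UIR 1 (0.22) or PTCKO UIR 3 (0.25). For UIR against sham the direction of Wwp2 depended on scaling, at -0.56 in WT and -0.28 in PTCKO with TMM and 0.15 and 0.23 without scaling. An exact two-sided permutation test with genotype exchanged within surgery gave a mean log2 difference of 0.11 (p = 0.115, 400 permutations). The values count reads over the whole gene in tissue that holds many cell types, and which exon was floxed is not given in the sources used here, so they could not show a deletion limited to an exon in proximal tubule cells. Every direction between genotypes below therefore rests on the labels. Of the 8 NEDD4-family ligases tested, Hecw2 was lower in PTCKO after UIR (log2 fold change -0.90, SE 0.184, adjusted p = 0.00633).

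UIR in WT kidney lowered the transcripts of tubule transport and mitochondrial metabolism and raised those of matrix, inflammation and immune cells. All 38 proximal tubule markers fell (median log2 fold change -4.31), among them the organic anion transporter Slc22a8, from 333 ± 42.7 to 7.49 ± 2.89 FPKM (log2 fold change -6.19, SE 0.281), and Slc7a13, from 342 ± 33.7 to 7.33 ± 1.38 (SD, n = 3). All 76 nuclear-encoded OXPHOS genes fell (median -1.98), with Sdha at 285 ± 12.1 FPKM after sham and 84.7 ± 2.36 after UIR. All 37 fatty acid oxidation genes (median -2.68, such as Cpt2 and the transcription factor Ppara at -3.18 and -3.99), all 18 TCA cycle genes (-2.26) and all 8 gluconeogenesis genes (-4.24, with Pck1 from 1551 ± 119 to 63.9 ± 17.3 FPKM) fell, as did 20 of 23 antioxidant and ferroptosis genes. Markers of the distal convoluted tubule fell in 7 of 7 cases, those of the thick ascending limb in 6 of 8 and those of the collecting duct principal cell in 7 of 9, with the water channel Aqp2 from 102 ± 38.8 to 5.88 ± 3.26 FPKM. In the same order, 0, 1 and 1 of these markers rose. With TPM 5, 4 and 5 fell and 1, 1 and 2 rose. The medians of -2.28, -1.57 and -1.56 were then -1.28, -0.692 and -0.687.

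All 32 extracellular matrix and myofibroblast genes rose in WT after UIR (median log2 fold change 3.82), such as the gelatinase Mmp2, from 0.92 ± 0.202 to 92.9 ± 14.5 FPKM (SD, n = 3). Of 27 tubule injury genes 24 rose and 3 fell, with Vcam1 from 2.07 ± 0.4 to 145 ± 1.27. All 18 macrophage and monocyte markers (median 4.88), 13 T and NK cell markers (3.77), 22 interferon response genes (2.67) and 7 class II antigen presentation genes (3.66) rose, together with 25 of 26 chemokine and cytokine genes, 13 of 14 complement genes and 24 of 25 cell cycle genes. C1qb went from 25.5 ± 3.73 to 1120 ± 196 FPKM, and the chemokine Ccl2 from 0.47 ± 0.130 to 74.2 ± 2.26. The largest rises included Gpnmb (0.22 ± 0.131 to 261 ± 105, log2 fold change 9.51, and 10.10 without WT sham 2) and Trem2 (0.21 ± 0.141 to 92.3 ± 19.7), both known from lipid-handling macrophages, and Fcrls, Mmp3, Il1rn and Sprr2f, whose sham levels were at most 0.04 FPKM. The largest falls included Hpd (54.5 ± 8.03 to 0.17 ± 0.0529) and Azgp1 (143 ± 11.2 to 1.41 ± 0.371).

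Of 15322 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 12038 were called for UIR against sham in WT, 6458 higher and 5580 lower, and 6924 changed at least 2-fold. The higher share of calls, 53.6%, depended on scaling: it was 77.2% with limma on FPKM, 80.9% with TPM and 78.7% without scaling factors, and the median of all genes moved from 0.11 to 0.82 without scaling. The OXPHOS median of -1.98 was -1.27 without scaling, -1.10 with TPM and -1.08 with quantile normalisation, and the fatty acid oxidation median of -2.68 was -1.78 with TPM. Adjusted over the list alone, the counts were the same for every list named for UIR in WT or in PTCKO. Camera called 11 lists up and 16 down (OXPHOS adjusted p = 1.17e-23, proximal tubule 9.15e-19, extracellular matrix 9.12e-24), and with an estimated correlation none passed (adjusted p = 0.112 to 0.469).

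**Figure D2:**
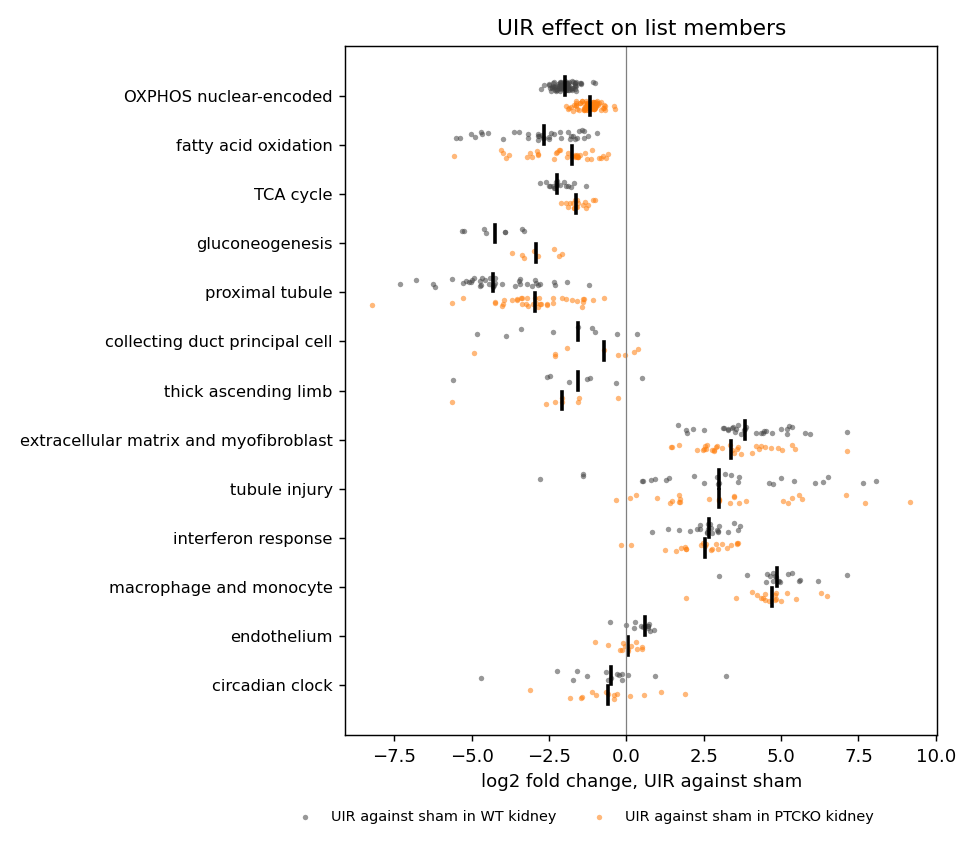
Log2 fold change of UIR against sham for each member of 13 gene lists, grey for WT and orange for PTCKO, with a black bar at each list's median. OXPHOS medians are -1.98 in WT and -1.17 in PTCKO, and proximal tubule medians -4.31 and -2.94.

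UIR in the libraries labelled PTCKO also lowered tubule and mitochondrial transcripts and raised those of matrix and immune cells. All 38 proximal tubule markers (median log2 fold change -2.94), 76 OXPHOS genes (-1.17) and 37 fatty acid oxidation genes (-1.76) fell, with Slc22a8 from 210 ± 32.8 to 18.4 ± 3.47 FPKM and Sdha from 284 ± 7.56 to 110 ± 8.11 (SD, n = 3). All 32 extracellular matrix genes rose (3.38), with Mmp2 from 1.03 ± 0.325 to 63.9 ± 8.56 FPKM, as did 24 of 27 tubule injury genes (3.00, the hyaluronan receptor Cd44 at 27.2 ± 3.55 after UIR), all 18 macrophage markers (4.70) and all 7 B and plasma cell markers tested (3.01, camera adjusted p = 0.111). Kdr, the endothelial VEGF receptor, fell (-1.0, SE 0.128), while the endothelial list had 4 members higher and 2 lower of 13 and its median of 0.04 was 0.56 without scaling, 0.51 with limma on FPKM, 0.54 with TPM and -0.07 with quantile normalisation. The largest rises named by the rule, such as Retnla (0.09 ± 0.0751 to 199 ± 171), Il1f6 (0 to 18.5 ± 3.71) and Cxcl5 (0.01 ± 0.0231 to 13.3 ± 4.41), started at or near 0. The largest falls included C8a (9.86 ± 1.70 to 0.11 ± 0.106 FPKM), Slc22a7 (140 ± 76.8 to 0.67 ± 0.420) and the beta-globin gene Hbb-b2 (10.3 ± 10.6 to 0.16 ± 0.178). The groups overlapped in FPKM of Hbb-b2, with PTCKO sham 2 at 0.34 and PTCKO UIR 1 at 0.35. The log2 fold change of C8a went from -6.81 to -7.56 without PTCKO UIR 2, and that of Slc22a7 from -8.21 to -8.85 without PTCKO UIR 3.

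By edgeR's test 11305 genes were called in PTCKO, 5969 higher and 5336 lower, and 5900 changed at least 2-fold. The higher share, 52.8%, was 75.8% with limma on FPKM, 76.5% with TPM and 77.2% without scaling factors. The OXPHOS median of -1.17 was -0.66 without scaling, -0.64 with limma on FPKM, -0.63 with TPM and -0.71 with quantile normalisation. Camera called 11 lists up and 14 down, and 6 kept their call with an estimated correlation (extracellular matrix, TGF-beta, tubule injury, chemokines, complement and macrophage, each adjusted p = 0.0499), while OXPHOS (adjusted p = 0.374) and proximal tubule (adjusted p = 0.173) did not. Of the genes called in both genotypes, 5265 rose in both (2516 by chance for independent lists) and 4634 fell in both (1943). Over genes called in WT, the slope of the PTCKO on the WT log2 fold change was 0.82 (jackknife SE 0.0573, 0.78 to 0.84 on leaving out each library). It was 0.85 over genes called in PTCKO. The reverse slope, of the WT on the PTCKO log2 fold change, was 1.075 over genes called in WT and 1.037 over genes called in PTCKO. The slopes describe genes, which are not independent replicates.

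After UIR, the libraries labelled PTCKO held more transcripts of proximal tubule and mitochondrial metabolism than WT. Of 38 proximal tubule markers 33 were higher (36 adjusted over the list alone, median log2 fold change 1.18), with the cystine transporter subunit Slc7a9 at 15.9 ± 4.5 FPKM in WT and 40.2 ± 5.81 in PTCKO, the endocytic receptor Cubn at 2.63 ± 0.894 and 7.85 ± 1.81, and Slc13a1 at 51.8 ± 16.5 and 143 ± 29.5 (SD, n = 3). Of 76 OXPHOS genes 47 were higher and 0 lower (72 higher adjusted over the list alone, median 0.44): 21 of 36 in complex I, 4 of 4 in complex II, 7 of 9 in complex III, 6 of 12 in complex IV and 9 of 15 in complex V. Ndufv1 of complex I was at 66.6 ± 7.08 FPKM in WT and 99.5 ± 12.8 in PTCKO (log2 fold change 0.65, SE 0.119, adjusted p = 0.00361), and Sdha of complex II at 84.7 ± 2.36 and 110 ± 8.11. Of 37 fatty acid oxidation genes 19 were higher (27 over the list alone, Ppara at 1.23, SE 0.167), of 18 TCA cycle genes 15 (18), of 8 gluconeogenesis genes 6 (8, Fbp1 at 1.55) and of 23 antioxidant and ferroptosis genes 10 (12, with 1 lower). Shorter transcripts were higher in PTCKO in this comparison. Of 5 equal classes of transcript length the shortest had a median of 0.15 and the longest -0.09. With a trend on length and GC content removed, the OXPHOS median was 0.28 and the proximal tubule median 1.2.

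Markers of other cell types moved both ways after UIR. Of 9 collecting duct principal cell markers 5 were higher in PTCKO (6 over the list alone, median 0.67), with the sodium channel subunit Scnn1b at 21.5 ± 2.24 FPKM in WT and 32.6 ± 3.39 in PTCKO. Of 13 endothelial markers 11 were lower (13 over the list alone, median -0.48), with Pecam1 at 41.6 ± 3.97 and 28.5 ± 1.67 and Tie1 at 20.6 ± 0.777 and 12.6 ± 0.862. Of 32 extracellular matrix genes 10 were lower (16 over the list alone, median -0.39), with the smooth muscle actin Acta2 at 138 ± 5.12 and 86.2 ± 16.4 FPKM, of 22 interferon response genes 8 (13, Ifi44 at 15.5 ± 1.53 and 7.57 ± 1.45), and of 18 macrophage and monocyte markers 7 (9, Cd68 at 268 ± 57.8 and 141 ± 32.2). Among TGF-beta genes Ccn2 was lower (257 ± 33.5 to 103 ± 47.1) and Bmp7 higher (6.49 ± 0.244 to 9.06 ± 0.593), with 2 higher and 4 lower of 22 (2 and 5 over the list alone). Of 27 tubule injury genes 5 were higher and 3 lower (7 and 3 over the list alone). Havcr1, the KIM-1 injury marker, was at 48.5 ± 6.78 FPKM in WT and 163 ± 39.5 in PTCKO (log2 fold change 1.82, SE 0.247, adjusted p = 0.000905), and Anxa1 at 176 ± 27.3 and 92.4 ± 7.69. By edgeR, 0 of 13 T and NK cell, 0 of 7 class II antigen presentation and 0 of 25 cell cycle genes were called (0, 0 and 1 at an unadjusted p under 0.05).

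The largest rises in PTCKO against WT after UIR were Cyp4f18 (1.09 ± 0.113 to 7.54 ± 1.04 FPKM), Calb1 (4.05 ± 2.00 to 27.8 ± 20.1), B3gnt3, Aqp2 (5.88 ± 3.26 to 29.6 ± 22.1), the fibrinogen genes Fgg (4.08 ± 2.40 to 20.4 ± 8.27) and Fga, Cyp4a12a and the clock output gene Dbp (6.10 ± 1.78 to 29.5 ± 8.03). The largest falls were Hbb-b2 (46.5 ± 12.7 to 0.16 ± 0.178, with WT sham 3 at 0.38 and PTCKO sham 2 at 0.34), Hbb-b1 (582 ± 166 to 1.93 ± 1.04), the glucocorticoid-induced transcription factor Zbtb16 (8.14 ± 1.88 to 0.71 ± 0.189), Gpnmb (261 ± 105 to 43.8 ± 35.7), Ms4a4a, Npy, the macrophage elastase Mmp12 (498 ± 156 to 124 ± 62.6) and the proteoglycan Lum. Of 15 circadian clock genes 7 were higher and 3 lower (8 and 3 over the list alone). Aqp2 lost its call without WT UIR 1 (log2 fold change 2.07) or PTCKO UIR 3 (1.59), Npy without the same libraries (-1.74 and -1.77), and Lum without WT UIR 1 (-1.47) or with limma at a pseudocount of 0.1 (-1.68). Calb1, at 2.86, was at 2.05 without PTCKO UIR 3, and Gpnmb, at -2.53, was at -3.36 without PTCKO UIR 2.

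By edgeR's test 2115 genes were called for PTCKO against WT after UIR, 1425 higher and 690 lower, and 498 changed at least 2-fold. Of the 1425 higher genes, 1303 were among those UIR lowered in WT (519 by chance for independent lists), and of the 690 lower genes, 628 were among those it raised (290.8). Both comparisons use the WT UIR libraries, which alone give a negative correlation of fold changes (-0.48 in 10 simulations of unchanged groups, -0.54 observed). Fold changes in unchanged groups are noise alone, so these correlations do not show how much of the observed opposition the shared libraries gave. The covariance was -0.50 against -0.03 simulated, and as the shared group has too few libraries to split, part of the excess may come from it. The count was 989 without WT UIR 1, 1230 without WT UIR 3, 1307 without PTCKO UIR 1, 3321 without PTCKO UIR 2 and 904 without PTCKO UIR 3, and the higher share of 67.4% was 52.4% with limma on FPKM, 48.2% with TPM, 51.0% with quantile normalisation and 56.1% without scaling factors. With quantile normalisation the OXPHOS median of 0.44 was 0.285, and 23 extracellular matrix, 14 interferon response and 13 macrophage genes were lower. Without scaling 3 collecting duct markers were higher. Camera called 17 lists up and 9 down (OXPHOS adjusted p = 2.69e-19, proximal tubule 3.55e-32, endothelium 6.40e-11, extracellular matrix 9.49e-08). None passed with an estimated correlation (adjusted p = 0.331 for OXPHOS, 0.254 for proximal tubule, 0.189 for endothelium, 0.331 for extracellular matrix, and 0.189 to 0.536 over the called lists).

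**Figure D3:**
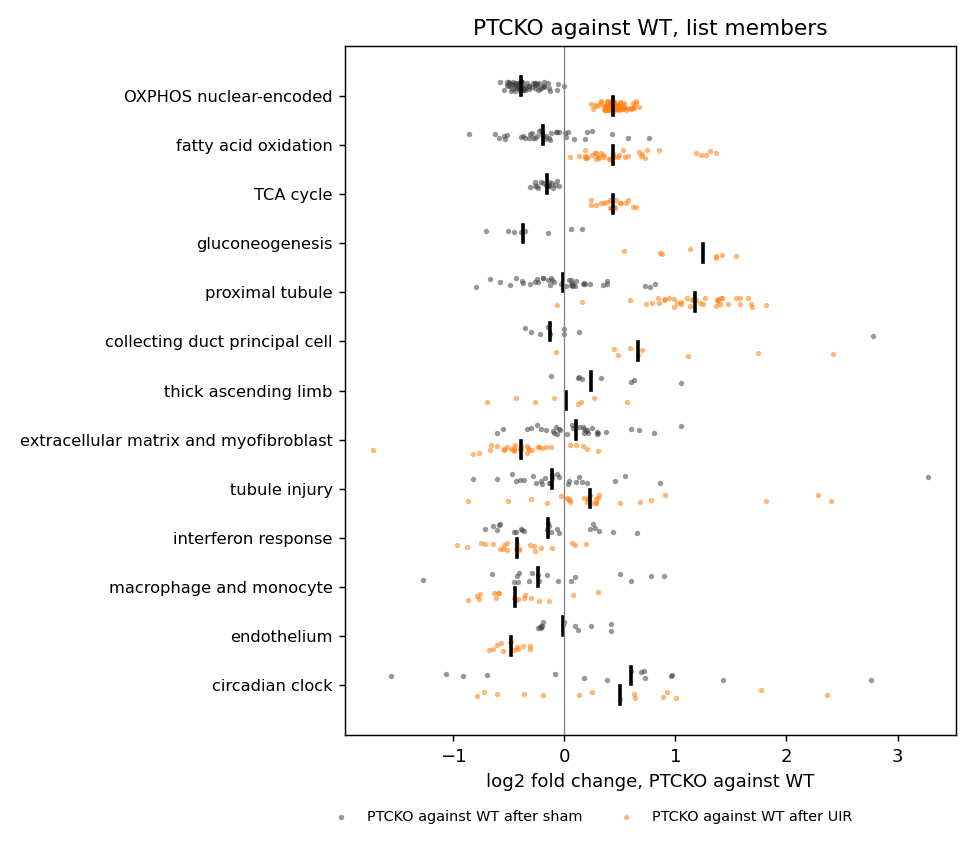
Log2 fold change of PTCKO against WT for each member of 13 gene lists, grey after sham and orange after UIR, with a black bar at each list's median. OXPHOS medians are -0.39 after sham and 0.44 after UIR, and proximal tubule medians -0.00695 (0.124 without scaling) and 1.18.

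**Figure D4:**
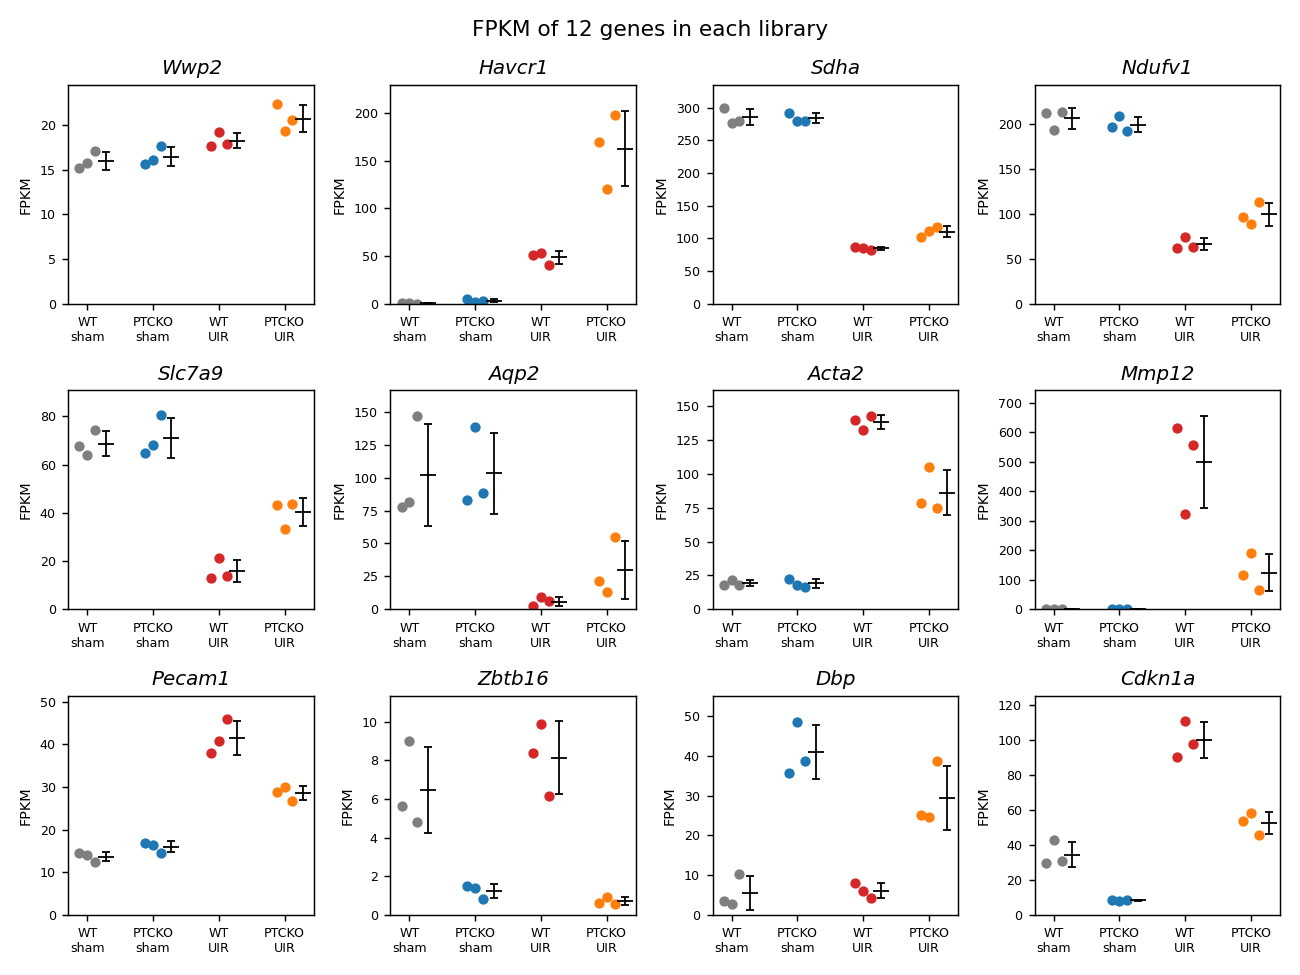
FPKM of 12 genes in each library by group, with the mean and SD (n = 3) drawn beside the points. Wwp2 is not lower in PTCKO, and Havcr1 is highest in PTCKO UIR (163 ± 39.5 against 48.5 ± 6.78 in WT UIR).

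After sham, clock, glucocorticoid-induced and OXPHOS genes were among those that differed between the libraries labelled PTCKO and WT. Of 15 circadian clock genes 6 were higher and 3 lower (9 and 4 adjusted over the list alone), with Dbp at 5.49 ± 4.2 FPKM in WT and 41.0 ± 6.76 in PTCKO (log2 fold change 2.76, SE 0.398, adjusted p = 0.00386), Per3 at 1.44 ± 0.338 and 4.29 ± 0.277, and the Bmal1 partner Npas2 at 5.96 ± 1.39 and 2.20 ± 0.405 (SD, n = 3). The largest falls included genes known to be induced by glucocorticoids: Zbtb16 (6.48 ± 2.22 to 1.23 ± 0.360), Cdkn1a, a cell cycle inhibitor (34.4 ± 7.27 to 8.32 ± 0.317), Depp1 and Arrdc2, beside Ppard, Noct and Prxl2b. Of 21 glucocorticoid-induced genes, a list written after 7 of them had been seen, 13 were lower and 0 higher (median -1.11), and of the 14 not seen before 7 were lower (median -0.72). Of 76 OXPHOS genes 15 were lower (50 over the list alone, median -0.39) and of 37 fatty acid oxidation genes 7 were lower and 1 higher (9 and 2 over the list alone, median -0.19, but 0.031 with TPM). Longer transcripts were higher in PTCKO sham, with a median of 0.17 in the longest of the 5 classes and -0.26 in the shortest. The OXPHOS median was -0.02 with the length and GC trend removed.

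Havcr1 was the tubule injury gene with the largest difference after sham, at 0.32 ± 0.202 FPKM in WT and 3.36 ± 1.48 in PTCKO (log2 fold change 3.27, SE 0.487, adjusted p = 0.00464), and 3 of 27 members were higher. Of 38 proximal tubule markers 2 were higher and 2 lower, and 0 of 32 extracellular matrix genes were called by edgeR (3 at an unadjusted p under 0.05). The largest rises were H3c14 (0 to 6.92 ± 2.39 FPKM), Akr1c18, Aqp4 (0.87 ± 0.807 to 6.56 ± 2.59), Dbp, Slc7a12, Mettl7a3, Cyp7b1 and Mettl7a2, of which Aqp4 and Dbp were called on leaving out each library (2.78 and 2.76, and 3.87 and 3.63 without WT sham 3). The call was lost for H3c14 without WT sham 1 or 3 or PTCKO sham 2 or 3 (fitted against 0 counts, so no bound). It was lost for Akr1c18 without WT sham 1 or 2 or PTCKO sham 2 (2.07 to 2.76) and for Slc7a12 without WT sham 1 or 3 (2.12 to 2.46) or with quantile normalisation (1.42). It was lost for Cyp7b1 without WT sham 1 or 2 or PTCKO sham 1 or 2 (1.58 to 2.19) and for Mettl7a3 and Mettl7a2 without PTCKO sham 2 (1.80 and 1.62). Without WT sham 3 the values of Akr1c18, Cyp7b1, Mettl7a3 and Mettl7a2 were 5.01, 3.12, 2.85 and 2.91, and without PTCKO sham 3 that of Slc7a12 was 1.33. Prxl2b rested on WT sham 3, without which its log2 fold change of -2.18 was -0.56. Its call was also lost without any WT UIR or PTCKO sham library or PTCKO UIR 1 or 3 (-2.33 to -2.10), with the replicate block (-1.84), with limma on FPKM (-1.31, adjusted p = 0.107), and with TPM or quantile normalisation (-1.25 in both).

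By edgeR's test 1645 genes were called for PTCKO against WT after sham, 802 higher and 843 lower, and 212 changed at least 2-fold. The count was 753 without WT sham 1, 430 without WT sham 3, 504 without PTCKO sham 1, 524 without PTCKO sham 2 and 653 without PTCKO sham 3. The higher share of 48.8% was 79.5% with limma on FPKM, 92.4% with TPM and 84.4% without scaling factors. The OXPHOS median of -0.39, with 15 genes lower, was -0.255 without scaling (4 lower), -0.15 with TPM (1) and -0.11 with quantile normalisation (0). Camera called 1 list up (clock, adjusted p = 0.0213) and 10 down (OXPHOS, adjusted p = 2.16e-15), each at adjusted p = 0.947 with an estimated correlation. With quantile normalisation the fatty acid oxidation and TCA cycle lists turned direction (adjusted p = 0.942 and 0.159). Of genes higher in PTCKO after UIR, 159 were lower in PTCKO after sham (78.4 expected) and 66 higher (74.59 expected).

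The UIR effect itself differed between genotypes for 3288 genes by edgeR's interaction test, 2203 with a more positive and 1085 with a more negative effect in PTCKO, and by at least 2-fold for 848. Of 76 OXPHOS genes 73 had a more positive effect in PTCKO (75 over the list alone, median 0.81), of 38 proximal tubule markers 27 (32, median 1.19), of 37 fatty acid oxidation genes 24 (30, median 0.70) and of 8 gluconeogenesis genes 7 (7, median 1.58). Ndufa6 of complex I fell from 382 ± 6.47 to 161 ± 26.9 FPKM in WT and from 286 ± 28.1 to 211 ± 19.0 in PTCKO (difference 1.001, SE 0.171, adjusted p = 0.00358, SD, n = 3). Of 13 endothelial markers 5 (8 over the list alone) and of 32 extracellular matrix genes 6 (11) had a more negative effect, with the small proteoglycan Dcn at -1.28 (SE 0.324). Part of the OXPHOS difference was present after sham, as the PTCKO against WT median was -0.388 after sham and 0.444 after UIR. The OXPHOS median of the interaction was 0.27 with the length and GC trend removed, 0.45 with TPM and 0.38 with quantile normalisation (26 genes more positive). The fatty acid oxidation median was 0.34 with TPM (12) and 0.42 with quantile normalisation (13). Without scaling 11 endothelial and 18 extracellular matrix genes had a more negative effect.

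The count of 3288 was 2186 without WT sham 3, 1743 without WT UIR 1, 2054 without PTCKO UIR 1 and 1743 without PTCKO UIR 3. The share with a more positive effect, 67.0%, was 34.3% with limma on FPKM, 18.8% with TPM, 54.1% with quantile normalisation and 32.1% without scaling factors. The median of all genes, -0.00151, was -0.29 with TPM and -0.03 with quantile normalisation. Camera called 13 lists up and 4 down (OXPHOS adjusted p = 2.96e-28, proximal tubule 3.24e-16), and none with an estimated correlation (adjusted p = 0.404 for OXPHOS and proximal tubule, 0.491 for extracellular matrix).

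Beta-globin usage differed between libraries. The share of Hbb-b1 plus Hbb-b2 in all beta-globin counts was 52.9%, 99.6% and 2.45% in WT sham, 53.6%, 54.0% and 99.5% in WT UIR, 52.5%, 1.10% and 48.1% in PTCKO sham, and 0.593%, 0.0887% and 0.201% in PTCKO UIR. Exact binomial 95% intervals (Clopper-Pearson), which cover counting error only, were widest in PTCKO sham 3, from 46.0% to 50.3%. In the other libraries near 50% they ran from 51.0% to 54.0% in PTCKO sham 1, 51.2% to 54.6% in WT sham 1, 52.5% to 54.6% in WT UIR 1 and 53.2% to 54.8% in WT UIR 2. In PTCKO UIR they ran from 0.378% to 0.893%, 0.0406% to 0.168% and 0.135% to 0.279%, in WT sham 3 from 1.97% to 3.04% and in PTCKO sham 2 from 0.827% to 1.46%. They ran from 99.4% to 99.8% in WT sham 2 and 99.3% to 99.7% in WT UIR 3. The remaining beta-globin counts came from Hbb-bs (chromosome 7, 103826523 to 103827928, GRCm38.p6) and Hbb-bt.

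**Figure D5:**
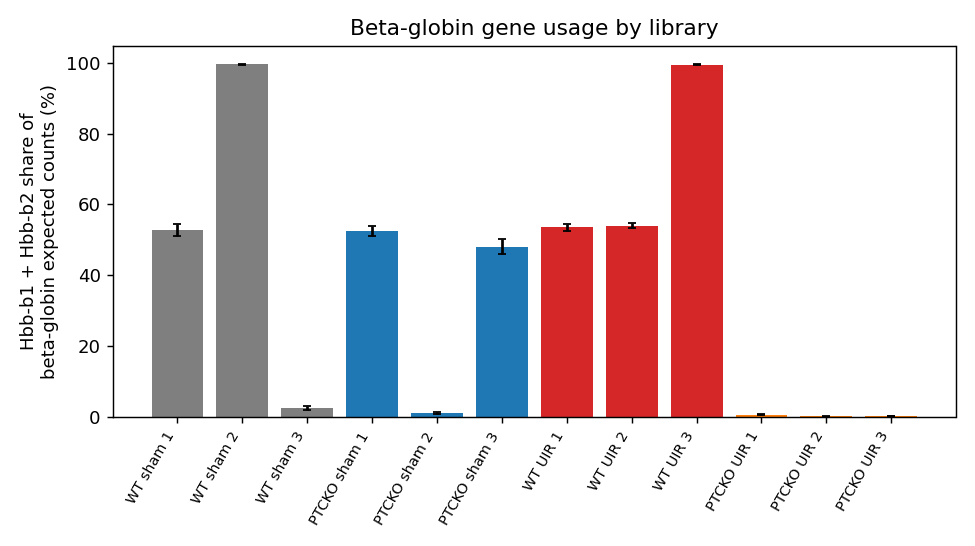
Share of Hbb-b1 plus Hbb-b2 in beta-globin expected counts (%), one bar per library coloured by group, with exact binomial intervals. All 3 PTCKO UIR libraries lie under 1%, and each other group holds a library near 50%.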

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

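The beta-globin and cell-type tests were chosen only after the results were seen, and the trend on length and GC content and the fit without scaling factors were added after the data were seen.

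The UIR effect differed between genotypes by the interaction test of edgeR for 3288 genes. Camera called the difference, given as the median log2 difference (PTCKO minus WT), for complexes I (0.83), II (0.644), III (0.804), IV (0.885) and V (0.76) and all OXPHOS genes (0.81), fatty acid oxidation (0.695), the TCA cycle (0.616), glycolysis (0.346), gluconeogenesis (1.58), antioxidant and ferroptosis (0.493), proximal tubule (1.19) and collecting duct principal cell (0.835). It also called extracellular matrix (-0.484), interferon response (-0.212), endothelium (-0.475) and macrophage and monocyte (-0.422). With quantile normalisation the medians were 0.446, 0.231, 0.359, 0.409 and 0.255 for complexes I to V and 0.231 for the TCA cycle, where 17 of 36, 0 of 4, 3 of 9, 4 of 12, 2 of 15 and 2 of 18 genes were called. With TPM the medians were -0.00651 for glycolysis, 0.138 for antioxidant and ferroptosis, 0.498 for collecting duct, -0.795 for extracellular matrix, -0.526 for interferon response, -0.817 for endothelium and -0.639 for macrophage and monocyte. The OXPHOS median was 0.265 with the length and GC trend removed. The OXPHOS difference joins a PTCKO against WT median of -0.388 after sham to one of 0.444 after UIR. With an estimated correlation none was called (adjusted p = 0.404 to 0.67). In 100 draws of the 200 exchanges of genotype within sham and within UIR, 1, the real one, called as many genes (highest other 2281). The exchange with 2281 genes kept only the sham libraries in their true groups, and the 82 that mixed genotypes in both surgeries called 0. The 11 that kept only the sham groups called 4 to 2281 genes, the next highest being 16. The 6 that kept only the UIR groups called 39 to 252. The exchange can therefore respond to a genotype difference within 1 surgery. Whether chance gives such a count of differing UIR effects was not decided by it.

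Single genes whose UIR effect was more positive in PTCKO by the interaction test were Cyp4f18 (3.443), Fga (3.108), Calb1 (3.076), Ftcd (2.918), Fgg (2.874), Acaa1b (2.164), Slc22a8 (2.161), Hlf (1.594), Khk (1.59), Gpx1 (1.404), Cdkn1a (1.306), Etfb (1.229), Ndufa6 (1.001), Slc7a8 (0.8496) and Ndufb3 (0.804). More negative were Npy (-3.477), Bcat1 (-3.452), Slc12a1 (-1.749), Dcn (-1.281), Csf1r (-1.085), Tek (-0.7918) and Smurf2 (-0.6822). All of these were called on leaving out each library. Bcat1 was at -4.39 without WT sham 3 and -2.77 without PTCKO sham 2, Calb1 at 2.26 without PTCKO UIR 3, and Npy at -2.44 without PTCKO sham 2. H3c14 (-17) was also called each time, but had 0 counts in WT sham and in PTCKO UIR, so its fitted value sets no bound. Its FPKM was 2.60 ± 2.31 in WT UIR and 6.92 ± 2.39 in PTCKO sham (SD, n = 3). Interaction values also carry any genotype difference present after sham. Cdkn1a was lower in PTCKO in both surgeries (-2.171 after sham, -0.865 after UIR), while Hlf differed mainly after UIR (0.1783 and 1.772). Summed counts of Bcat1 were 300 in WT sham, 1694 in PTCKO sham, 2907 in WT UIR and 1332.69 in PTCKO UIR. Those of Slc12a1, in the same order, were 18836, 40795, 27878 and 15961.

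Other calls of a differing UIR effect rested on particular libraries. H2bc23 (9.888) lost its call without WT sham 2, WT UIR 1 or any PTCKO sham library (1.10 to 12.94, and 10.48, 13.73 and 8.98, still called, without WT sham 1, WT UIR 2 and PTCKO UIR 2). Its FPKM was 5.80 ± 10.1 in WT sham, 0.06 ± 0.104 in WT UIR, 0.08 ± 0.139 in PTCKO sham and 5.12 ± 4.82 in PTCKO UIR (SD, n = 3). Sirpb1b (5.316) lost its call without WT sham 2 or 3, WT UIR 1, any PTCKO sham library, or PTCKO UIR 1 or 3 (4.56 to 5.37, and 5.93, still called, without WT sham 1). It was at 0.13 ± 0.126 FPKM in WT sham, 4.26 ± 0.801 in WT UIR, 0 in all PTCKO sham libraries and 5.47 ± 0.179 in PTCKO UIR. PTCKO sham held 0 counts of Sirpb1b and 2.08 of H2bc23, so these fitted values set no bound. Jchain (3.089) lost its call without WT sham 2, WT UIR 1 or 2, PTCKO sham 2 or 3 or PTCKO UIR 1 (1.74 to 3.02) and was at 3.73, still called, without WT UIR 3. Ugt1a6b (2.91) lost it without WT sham 1 or 3, WT UIR 1 or 2, any PTCKO sham library, or PTCKO UIR 1 or 3 (2.02 to 3.15) and was at 4.16, still called, without WT UIR 3. Slc4a11 (-3.145) lost it without WT sham 1 or 3, any WT UIR library, PTCKO sham 2, or PTCKO UIR 1 or 3 (-3.34 to -1.72). Serpina1c (-2.954) lost it without WT UIR 1 (-2.74) or PTCKO UIR 3 (-2.48). Lum (-2.773) lost it without WT sham 1, WT UIR 1, PTCKO sham 1 or 2, or PTCKO UIR 1 or 3 (-2.77 to -2.19), and Fn1 (-0.9312) without WT UIR 1, PTCKO sham 1 or 2, or PTCKO UIR 1 or 3 (-0.91 to -0.85). With limma on FPKM the call was lost for H2bc23 (3.31), Jchain (2.37) and Slc4a11 (-1.25), and at a pseudocount of 0.1 for Sirpb1b (1.41) and Ugt1a6b (2.65). With the replicate block it was lost for Slc4a11 (-2.91) and Lum (-2.71).

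Hbb-b1 (-7.365, -8.48 without WT sham 2, -6.29 without PTCKO sham 1) and Hbb-b2 (-7.479, lost without PTCKO sham 1, -6.31, or PTCKO UIR 3, -7.31, and -8.36, -8.75 and -6.85, still called, without WT sham 2, PTCKO UIR 1 and PTCKO UIR 2) were near 0 in all 3 PTCKO UIR libraries. An effect of knockout with injury is argued against, since 2 libraries of other groups, WT sham 3 and PTCKO sham 2, also had a share of these genes under 10%. The share lay within 15 points of 0, 50 or 100% in 12 of 12 libraries, as 2 beta-globin haplotypes segregating among the mice may give. The labels state a C57BL/6J background, and C57BL/6 mice are known to carry Hbb-bs and Hbb-bt. Genes within 10 Mb of Hbb-bs passed an unadjusted p under 0.05 for the haplotype dosage in 25 of 155 cases against 811 of 15125 elsewhere (ratio 3.01, one-sided Fisher exact p = 1.06e-06, neighbouring genes not being independent), a test respecified after 0 genes were called by edgeR after adjustment. The beta-globin share ran from 53.6% to 99.5% in WT UIR and from 0.0887% to 0.593% in PTCKO UIR. In PTCKO against WT after UIR it therefore cannot be told apart from the labelled genotype. After sham the groups overlapped, at 2.45% to 99.6% in WT and 1.1% to 52.5% in PTCKO. A mixed background not balanced across groups stays open as a hypothesis, and its share in other genotype differences was not tested.

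After UIR, proximal tubule and OXPHOS transcripts were higher in PTCKO. A larger share of proximal tubule RNA alone would move the markers of other cell types by equal amounts. The mean log2 CPM of collecting duct minus endothelial markers was -1.36 ± 0.362 in PTCKO UIR and -2.69 ± 0.359 in WT UIR (SD, n = 3). These were 1.33 apart (SE 0.295 between libraries, 1.14 to 1.54 on leaving out 1) with no overlap. Such a gap argues against that share as the only difference between these groups. It cannot show whether the proximal tubule and OXPHOS rises came from a change in cell composition. Neither the collecting duct nor the endothelial list was called by camera with an estimated correlation (adjusted p = 0.331 and 0.189). With 3 against 3 libraries no exact permutation p under 0.1 is possible. Library scaling alone is argued against by an OXPHOS median of at least 0.285 over the scalings tried (lowest with quantile normalisation, where library medians differed by 0.281, SE 0.0795). A length and GC trend as the whole cause is argued against by a median of 0.278 after its removal (0.444 before, and 0.261 with SE 0.0772 between libraries when removed in each library), though after sham the median rose from -0.388 to -0.0152, so there the trend may account for the lower OXPHOS level. An effect of the genotype on injury, a change in cell composition, an unbalanced background and a milder injury in these mice are among the explanations that stay open. They were not tested, and the list is not complete.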

How the results depend on the processing

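The fit without scaling factors was chosen after the data were seen. Over the 5 gene counts, 57 values in other settings stayed within 1.5 times and 12 moved further, and on leaving out 1 library 46 stayed and 14 moved. Requiring a 2-fold change gave 6924, 5900, 498, 212 and 848 genes for UIR in WT, UIR in PTCKO, PTCKO against WT after UIR, PTCKO against WT after sham, and the interaction, by construction fewer. A mean FPKM of at least 5 left fewer genes to test and gave 7747 and 7272 for UIR in WT and in PTCKO. Array weights gave 4807 after UIR, 3304 after sham and 6265 for the interaction, and after sham TPM gave 2633 and quantile normalisation 469, and the cause was not tested. Leaving out 1 library gave 11523 to 12216 for UIR in WT, 10675 to 11494 in PTCKO, 904 to 3321 after UIR, 430 to 2183 after sham and 1743 to 4565 for the interaction, with fewer samples. The slope of the PTCKO on the WT UIR effect stayed between 0.78 and 0.85 in every setting tried. With an estimated correlation, adjusted p was 0.331 for OXPHOS and for extracellular matrix after UIR, and 0.404 and 0.491 for the interaction, where fry gave 0.0623 for extracellular matrix. After sham with quantile normalisation the fatty acid oxidation list (adjusted p = 0.942) and the TCA cycle list (0.159) reversed, and the cause was not tested. Wwp2 in PTCKO against WT after UIR ranged from 0.2223 to 0.32 on leaving out 1 library, and its call was lost without scaling (0.1822), with limma on FPKM with pseudocounts of 1 (0.1722) and 0.1 (0.18), with TPM (0.122), with quantile normalisation (0.2091) and with the replicate block (0.2498). Wwp2 after UIR against sham reversed with scaling: in WT from -0.56 to 0.1526 without scaling, 0.1794 and 0.1889 with limma on FPKM, and 0.3504 with TPM, and in PTCKO from -0.28 to 0.2336, 0.3142, 0.3295 and 0.3369. These settings differ from TMM in how far the median of all genes moves. Among the 217 named gene and comparison pairs, Wwp2 in PTCKO against WT was counted apart. Its call was weakened in 5 results in other settings and in 6 on leaving out 1 library. For the remaining pairs, other settings weakened the call in 34 results and reversed 8, all of them Wwp2 for UIR against sham. Leaving out 1 library weakened 139, strengthened 1 and left 2440 the same. Of the list results, other settings weakened 160, strengthened 55 and reversed 2. The replicate block gave 12044, 11302, 1983, 1667 and 3274 genes. Replicate numbers do not pair the libraries: correlations of same-numbered libraries ran from -0.0856 to 0.165, with 2 of 18 over 0.1, and 4 of 12 libraries correlated best with their own number. The block ended the calls of Wwp2 after UIR, of Prxl2b after sham and of Slc4a11 and Lum in the interaction, and 2 list calls, and changed no other call of a named gene, list or count. With 3 against 3 libraries only 10 splits exist, too few for a share under 0.05. The real counts were 12038, 11305, 2115 and 1645, and the highest other counts 0, 0, 1 and 0. Every other split mixed the groups compared, which puts their difference into the spread within groups. Low counts there were to be met with and do not test chance. At this depth and replicate number the simulation, with 196 of 14960 genes changed, recovered 4.08% of 1.5-fold interaction changes. In the data 3288 genes were called for the interaction. Adjusted p depends on how many genes change, so this share does not carry over to the data.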

Other observations

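The clock and glucocorticoid tests below were chosen after the result was seen.

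Lists not described so far also moved with UIR in WT kidney. Of 19 genes of mitochondrial biogenesis and dynamics 15 fell and 1 rose (median log2 fold change -1.25, but -0.534 with 12 lower and 5 higher without scaling), with the nuclear receptor Esrra from 55.8 ± 1.78 to 19.9 ± 1.59 FPKM (SD, n = 3), and after UIR 4 were higher in PTCKO, Esrra and Sirt3 among them (0.39 and 0.61). Of 18 glycolysis genes 5 rose and 12 fell (7 and 9 without scaling, 9 and 9 with TPM), with Hk2 at 5.31 (5.89 without WT sham 2) and Pgk1 at -2.19, so the list did not move one way. Of 22 TGF-beta genes 19 rose and 2 fell. Of 19 apoptosis and necroptosis genes 15 rose, with the inflammatory caspase Casp4 at 4.5, and of 21 p53 and senescence genes 12 rose and 6 fell (17 and 3 without scaling, 16 and 2 of 20 with TPM), while in PTCKO after UIR 1 was higher and 6 lower, with Cdkn1a at 99.8 ± 10.2 in WT and 52.4 ± 6.43 in PTCKO. Camera calls in WT were lost with an estimated correlation (adjusted p = 0.125 for biogenesis, 0.469 for glycolysis and 0.163 for apoptosis).

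Among NEDD4-family ligases UIR lowered Wwp1 in WT (-1.71, SE 0.0938) and raised Smurf1 (1.48) and Nedd4 (0.79), and 3 of 8 were higher and 4 lower (4 and 1 without scaling). Podocyte markers rose in 8 of 9 cases, intercalated cell markers rose in 2 and fell in 6 of 8 (median -0.419, but 0.293 with 4 higher and 2 lower without scaling), and neutrophil markers rose in 4 and fell in 1 of 7 (2 and 2 of 5 with quantile normalisation). After UIR, 3 of 8 intercalated cell markers (Atp6v0d2, 68.4 ± 11.7 in WT and 33.6 ± 8.47 in PTCKO) and 2 of 9 podocyte markers were lower in PTCKO, and 3 of 7 B and plasma cell markers were higher (0 of 5 with limma on FPKM). Of 6 erythrocyte markers and 4 sex-linked genes, 0 were called by edgeR over all genes in PTCKO against WT in either surgery (erythrocyte 0 in both at an unadjusted p under 0.05, sex-linked 1 after UIR and 4 after sham), while adjusted over the list alone 3 sex-linked genes were higher and 1 lower after sham. Of 17 immediate-early and heat shock genes 3 were lower in PTCKO after UIR and 1 after sham (0 over the list alone). With an estimated correlation the calls in PTCKO against WT after UIR were lost (adjusted p = 0.447 for intercalated and for B and plasma cells, 0.394 for podocytes, 0.443 for immediate-early genes and 0.331 for p53 and biogenesis).

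Across 15 clock genes, which are not independent replicates, the PTCKO minus WT log2 fold changes after sham and after UIR, from libraries that are not shared, correlated with r = 0.765 and rho = 0.625 (permutation p = 0.0011), 13 with the same sign, against -0.12 over all genes. The interaction test of edgeR called 3 of the 15, among them Hlf (0.18 after sham, 1.77 after UIR) and Bhlhe41 (0.96 and -0.36). A different clock phase at collection is a candidate explanation, and collection times were not among the labels analysed here, so an effect of the genotype on the clock stays open and untested. Of 21 glucocorticoid-induced genes, 5 also in other lists, 14 had not been seen before the list was written. Their median was -0.722 after sham, where 0% of 10000 random lists matched on expression lay as low. After UIR it was -0.0854, where 0.83% did and 3 genes were lower. The random lists drew each gene independently, while genes with a shared inducer may move together. These percentages therefore do not measure the spread between libraries. Over all 21 genes the medians were -1.11 and -0.233. Higher glucocorticoid exposure in the WT mice, from handling or time of day, may account for this, and the test does not separate it from a genotype effect.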
